A study of Mus musculus with 36 samples.

How the data were processed

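Total RNA of liver, spleen and thymus was sequenced by the submitters from mice with wild-type p53 (wt) and with a deletion of the p53 C-terminus (d24). Per the labels, tissue pieces were kept in RNAlater, RNA was extracted with the RNeasy Mini kit and libraries were made with the TruSeq Stranded Total RNA kit. The titles give 36 libraries in 12 groups of 3. The 18 paired-end libraries are wt tissues without treatment or after X-rays, and the 18 single-end libraries are d24 and wt tissues titled xray. The characteristics give 2 Gy and 3 h for the irradiated libraries, but control for 9 libraries titled xray and WT for the 9 titled d24. Groups were taken from the titles. The labels do not name the animals or say whether tissues came from the same ones.

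Each layout has its own deposited table of normalised signal per gene. In both, the deposited signal is reads per gene per 1000000 reads of an effective library size, that is CPM with a composition factor per library. All values were whole multiples of 1 step per column (tolerance 0.01 of a step), and the geometric mean of the column totals was 1000000, the form that edgeR's TMM scaling gives. The design assumed plain CPM, so the unit differs from it by that factor, and the test planned for normalised values was used. The submitters' processing notes name edgeR and the build mm10, with no version. The aligner, the counting tool and its use of strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could not be assigned further. The paired-end table was normalised over 36 columns, of which 18 match no library of this series and were not used here. Its 19001 rows and the 17697 of the single-end table are genes given by number, of which 18380 (96.7%) and 17186 (97.1%) were matched to a symbol and coordinates in the RefSeq annotation of GRCm38. A column of gene names was filled for 3117 and 2442 rows and was not used.

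Depth was recovered from the size of the step. The paired-end libraries held 44348579 to 81322683 reads in the table and the single-end ones 20481048 to 38042710. A single read was worth 0.00991 to 0.0828 units of signal, and values near that size rest on few reads. Such counting limits leave out the variation between animals. Correlations between replicates ran from 0.975 to 0.993 in paired-end groups and from 0.876 to 0.982 in single-end groups.

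Genes with a signal of at least 1 in at least 3 libraries of a comparison were tested with limma 3.58.1 (eBayes with trend, R 4.3.3) on log2(signal + 0.5), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. X-ray against untreated was tested in each wt tissue of the paired-end table, and d24 against wt in each tissue of the single-end table, with no covariate. The interaction of X-rays or of genotype with tissue was tested by an F test over the 18 libraries of a table. Tables were not joined in any test. Gene lists, 43 in number, were tested with camera (preset correlation 0.01) where at least 5 members were measured, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The union of the 4 p53 target lists (70 genes) was tested on its own, so its p is its adjusted p. Of the lists that passed, the ones still passing with an estimated correlation were 0 of 11 in X-ray liver, 0 of 18 in X-ray spleen, 0 of 20 in X-ray thymus, 0 of 18 in d24 liver, 1 of 16 in d24 spleen and 0 of 20 in d24 thymus. Genes that X-rays raised by a log2 of at least 1 in the paired-end table were tested as a set in the single-end table. A library's position is the median over these genes of its distance from the untreated mean divided by the distance from the untreated to the X-ray mean, in log2. The library's median offset over all genes tested in both tables, taken from the midpoint of the untreated and X-ray means, was removed first. After the data were seen, positions were also taken over the p53 targets among these genes alone.

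The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names a panel of 11 genes in every comparison, the 7 highest and 7 lowest differences among genes that passed with an absolute log2 of at least 1, a mean of at least 5 in the higher group and no overlap between groups, up to 4 members of each passing list with the smallest p in its direction, and the 8 genes of smallest p in each interaction. Predicted gene models, pseudogenes, ribosomal and small RNAs and receptor gene segments were counted but not named.

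Alternatives were pseudocounts of 0.1 and 2, no filter and a mean of at least 5, median-ratio and quantile scaling, limma without trend, a replicate block, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, 1 fit of all libraries of a table, camera with an estimated correlation and leaving out each library. Added after the data were seen were Xist as a covariate for sex and leaving out libraries that stood apart. The replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. Every pair's correlation passed 0.1 in X-ray spleen (0.177, 0.241 and 0.191) and in no other comparison. The pairing there comes from the data, since the labels do not say what a number stands for. Between tissues, every same-numbered pair passed 0.1 in X-ray liver and spleen (0.314, 0.166 and 0.104). The same held in untreated spleen and thymus (0.151, 0.318 and 0.124) and single-end wt liver and spleen (0.316, 0.119 and 0.449). Pairs of unlike numbers there reached 0.169, 0.214 and 0.345. Tissues may thus share animals, while the interaction tests took their libraries as separate.

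The test was tried on simulated data with the spread of each comparison, in which 200 genes were changed. Limma recovered 66% of genes with a log2 change of 1 and 95% with a change of 2 in X-ray liver, 88% and 99% in X-ray spleen and 81% and 98% in X-ray thymus. In the d24 comparisons it recovered 11% and 58% in liver, 3% and 53% in spleen and 16% and 64% in thymus. The interactions gave 51% and 89% for X-rays and 0% and 30% for genotype. False calls were 2.60% to 11.1% of calls by limma and 11.5% to 40.0% by DESeq2. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.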

Results

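Mice with wild-type p53 (wt) and mice lacking the C-terminus of p53 (d24) were profiled by RNA sequencing of liver, spleen and thymus. The question named by the series title is what the C-terminus does to gene regulation in liver and to the response to radiation. The data held 12 groups of 3 libraries. A paired-end table held wt tissues without treatment and 3 h after 2 Gy of X-rays, and a separate single-end table held d24 and wt tissues that were all titled xray. Levels are the deposited normalised signal, shown as mean ± SD of 3 libraries, and differences are on the log2 scale, shown as ± SE. Both tables were normalised separately, so every test was made within 1 table. No d24 library titled untreated was analysed here.

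Trp53, the gene that carries the deletion, was measured first in every group. It encodes the transcription factor p53, and a C-terminal deletion need not change its total level, so its level does not check the genotype labels. In paired-end liver Trp53 was 38.7 ± 5.16 against 42.6 ± 3.68 (X-ray against untreated), in spleen 120.5 ± 17.4 against 122 ± 7.35 and in thymus 82.5 ± 4.00 against 96.9 ± 3.57. In the single-end table it was 46.8 ± 4.42 against 48.3 ± 11.9 in liver (d24 against wt), 198 ± 47.1 against 99.2 ± 7.76 in spleen and 122 ± 24 against 120.4 ± 11.5 in thymus. None of the 6 differences passed the test (limma, Benjamini-Hochberg adjusted p from 0.0503 in X-ray thymus to 0.99 in d24 thymus).

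A fixed panel of 10 p53 target genes was followed with Trp53 (GRCm38 coordinates). Trp53 lies on chromosome 11 from 69580348 to 69591873 and Ccng1 on chromosome 11 from 40748552 to 40755309. The cell cycle inhibitor Cdkn1a lies on chromosome 17 from 29090979 to 29100722, and Mdm2, whose product marks p53 for degradation, on chromosome 10 from 117688875 to 117710758. The death genes Bax (45461695 to 45466903) and Bbc3 (16308398 to 16318334) and the nuclease gene Aen (78895927 to 78911209) are on chromosome 7. Pmaip1 spans 66458604 to 66465558 on chromosome 18, Phlda3 135766085 to 135769134 on chromosome 1, Sesn2 132492804 to 132510456 on chromosome 4 and Eda2r 97333837 to 97377234 on chromosome X.

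In wt liver, X-rays raised a small set of p53 target genes. Cdkn1a rose from a mean of 14.5 ± 2.47 to 117 ± 8.73, a log2 difference of 2.97 ± 0.15. The death receptor gene Eda2r rose by 3.58 ± 0.20, Phlda3 by 2.64 ± 0.17, Ccng1 by 2.02 ± 0.14, Aen by 1.83 ± 0.16 and Sesn2 by 1.31 ± 0.17 (limma, Benjamini-Hochberg adjusted p from 0.000238 to 0.0173). The other panel genes did not pass, with Mdm2 at 0.78 ± 0.12, Pmaip1 at 0.95 ± 0.22, Bax at 0.56 ± 0.13 and Bbc3 at -0.27 ± 0.42. Outside the panel, Inka2 rose by 2.79 ± 0.23, the transcriptional repressor Bcl6 by 2.28 ± 0.19, Trp53inp1 by 2.18 ± 0.24 and the death receptor Tnfrsf10b by 2.07 ± 0.20. The named genes that fell were Cish, an inhibitor of cytokine signalling (-3.14 ± 0.34), and the hepatic transcription factor genes Onecut1 (-2.60 ± 0.25), Hhex (-2.19 ± 0.32) and Foxa2 (-1.03 ± 0.13).

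Of 63 measured members of the 4 p53 target lists, 14 rose and 0 fell in liver, or 24 and 1 when adjusted over the list alone. The median log2 difference was 0.23 (camera, adjusted p = 2.74e-10, and adjusted p = 0.0101 with an estimated correlation). That median was 0.11 without X-ray replicate 1, 0.13 with the stricter filter and 0.14 with Xist as a covariate for sex. The arrest and feedback list had 4 of 14 members up (8 adjusted over the list alone), among them Zmat3 (1.39 ± 0.16) and Btg2 (1.04 ± 0.15), with a median of 0.78 (camera, Benjamini-Hochberg adjusted p = 3.27e-09, and adjusted p = 0.0784 with an estimated correlation). In the apoptosis list, 5 of 15 members rose, including Apaf1 (1.22 ± 0.12), a core protein of the caspase-activating complex (camera, Benjamini-Hochberg adjusted p = 8.53e-07, and adjusted p = 0.0993 with an estimated correlation).

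Cell cycle genes lay lower in the irradiated livers as groups, though no member passed on its own. All 30 measured G2/M genes had a negative log2 difference, with a median of -0.85 (camera, Benjamini-Hochberg adjusted p = 1.5e-07, and adjusted p = 0.784 with an estimated correlation). Foxm1, a driver of mitotic genes, was at -1.14 ± 0.33 and the proliferation marker Mki67 at -0.98 ± 0.32, with 91.9 in X-ray replicate 1 beside 40.9 and 36.8 in the others and 81.5 to 126 in untreated livers. Erythroid markers lay lower in the same libraries, with 16 of 17 negative and a median of -0.69 (camera, Benjamini-Hochberg adjusted p = 0.0147, and adjusted p = 0.866 with an estimated correlation). The S phase list had a median of -0.63 over 27 genes, of which 4 were lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.34e-06, and adjusted p = 0.784 with an estimated correlation). Among 12 NF-kB genes the adhesion gene Icam1 rose by 1.11 ± 0.12, and 6 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.59e-06, and adjusted p = 0.176 with an estimated correlation). The unfolded protein response list, with the chaperone gene Hspa5 at 0.96 ± 0.28, had 11 of 18 members higher when adjusted over the list alone and 0 over all genes tested (camera, Benjamini-Hochberg adjusted p = 6.56e-05, and adjusted p = 0.784 with an estimated correlation). Clock genes varied within both liver groups, with Ciart at 8.29, 20.2 and 4.70 in the X-ray and 5.73, 1.84 and 0.303 in the untreated libraries, and that list had a median of 0.68 (camera, Benjamini-Hochberg adjusted p = 0.00424, and adjusted p = 0.784 with an estimated correlation).

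Over all genes, limma with Benjamini-Hochberg adjustment called 32 of 13250 in liver, 27 higher and 5 lower after X-rays, while 2902 had an unadjusted p under 0.05. DESeq2 called 631. Values of both groups did not overlap for 27.4% of genes, where chance gives 10%. The count was 17 without untreated replicate 1, 16 without untreated replicate 2, 13 without untreated replicate 3, 2836 without X-ray replicate 1 (933 higher and 1903 lower) and 9 without X-ray replicate 3. Hhex, Foxa2, Btg2, Icam1 and Trp53inp1 lost their calls without any 1 of the untreated libraries or X-ray replicate 3, where Hhex reached a Benjamini-Hochberg adjusted limma p of 0.28. Apaf1, Sesn2 and Zmat3 each lost theirs in 3 of these 4 refits, and Cish without X-ray replicate 3. Cdkn1a, Ccng1, Phlda3, Eda2r, Aen, Bcl6, Tnfrsf10b and Onecut1 were called without any 1 library.

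**Figure D1:**
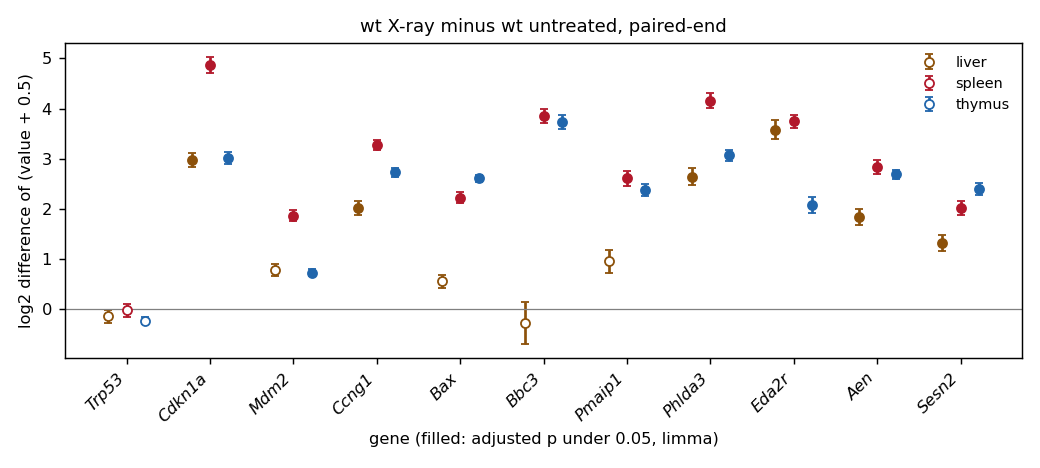
Log2 difference (X-ray minus untreated, ± SE, 3 against 3 wt paired-end libraries) of the 11 panel genes in liver, spleen and thymus, with filled points for Benjamini-Hochberg adjusted limma p under 0.05. Cdkn1a stood at 2.97 in liver, 4.87 in spleen and 3.01 in thymus, and Bbc3 at -0.27, 3.85 and 3.73.

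In wt spleen, X-rays raised every panel gene except Trp53. Cdkn1a went from 4.98 ± 1.29 to 157 ± 6.19, a log2 difference of 4.87 ± 0.16. Bbc3, which encodes the death protein Puma, went from 3.42 ± 0.636 to 55.8 ± 3.87 (3.85 ± 0.14), and Ccng1 rose by 3.28 ± 0.10 (limma, Benjamini-Hochberg adjusted p from 5.35e-07 to 6.58e-07 for these genes). Inka2 (4.52 ± 0.13), Zfp365 (4.37 ± 0.13), Phlda3 (4.16 ± 0.14), Prrg4 (3.90 ± 0.20) and the T cell costimulatory ligand gene Tnfsf4 (3.81 ± 0.15) were the other highest named genes. Mdm2 rose by 1.86 ± 0.11, Bax by 2.22 ± 0.11, Pmaip1 by 2.61 ± 0.15, Aen by 2.84 ± 0.14 and Sesn2 by 2.01 ± 0.14. The lowest named genes were Pklr (-3.19 ± 0.35), a pyruvate kinase gene of red cells and liver, Acsl6 (-3.12 ± 0.35), Prss50 (-2.68 ± 0.27), Gdf3 (-2.58 ± 0.34), Hpn (-2.34 ± 0.24), the copper transporter gene Atp7b (-2.34 ± 0.27) and the zinc transporter gene Slc39a8 (-2.32 ± 0.17).

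Of 65 measured p53 targets, 46 rose and 7 fell in spleen (47 and 8 adjusted over the list alone), with a median of 1.30 (camera, adjusted p = 7.34e-18, and adjusted p = 0.000384 with an estimated correlation). The apoptosis list had 12 of 14 members up, including Ei24 (2.27 ± 0.10), and the arrest list 10 up and 2 down of 16. Their medians were 2.31 and 1.52 (camera, Benjamini-Hochberg adjusted p = 4.36e-10 and 1.12e-05, and adjusted p = 0.0733 and 0.394 with an estimated correlation). In the S phase list 26 of 27 genes fell, including the replicative helicase gene Mcm4 (-1.30 ± 0.18), the licensing gene Cdc6 (-1.41 ± 0.20) and cyclin E1 gene Ccne1 (-1.90 ± 0.22). The list's median was -1.01 (camera, Benjamini-Hochberg adjusted p = 4.36e-10, and adjusted p = 0.528 with an estimated correlation). Of 30 G2/M genes, 1 rose and 3 fell, and that list did not pass (camera, Benjamini-Hochberg adjusted p = 0.144).

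Inflammatory and immediate early genes also rose in the irradiated spleens. All 13 measured NF-kB genes were called higher, among them Relb (1.78 ± 0.12), the inhibitor gene Nfkbia (1.88 ± 0.15), Tnfaip3 (2.19 ± 0.18) and Cd83 (2.50 ± 0.17), with a median of 1.68 (camera, Benjamini-Hochberg adjusted p = 4.36e-10, and adjusted p = 0.384 with an estimated correlation). Immediate early genes had 12 of 14 members up, with Jun at 1.63 ± 0.22 and Nr4a1 at 1.48 ± 0.19 (camera, Benjamini-Hochberg adjusted p = 1.44e-05, and adjusted p = 0.499 with an estimated correlation). Macrophage markers rose for 10 of 11 genes, including the complement gene C1qa (0.87 ± 0.16), and megakaryocyte markers for 6 of 9, including Itga2b (0.80 ± 0.14). For these marker lists camera gave Benjamini-Hochberg adjusted p = 9.66e-05 and 0.00382, and adjusted p = 0.499 and 0.566 with an estimated correlation. Markers of hepatocytes, a cell type of another organ, were higher in the same libraries. All 7 measured hepatocyte markers were called, with Ahsg at 35.1 ± 27.1 against 3.66 ± 1.51 and Ass1 at 1.53 ± 0.11 (camera, Benjamini-Hochberg adjusted p = 0.00382, and adjusted p = 0.573 with an estimated correlation). Ahsg lost its call without untreated replicate 1, untreated replicate 2 or X-ray replicate 3.

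In spleen, limma with Benjamini-Hochberg adjustment called 5351 of 13389 genes, 2614 higher and 2737 lower after X-rays. A log2 difference of at least 1 was met by 799 of them, 492 higher and 307 lower. Values did not overlap between groups for 53.3% of genes, where chance gives 10%. The count was 3463 without untreated replicate 1, 3238 without untreated replicate 2 and 3136 without X-ray replicate 3. The spleen panel genes except Trp53 were called in every refit without 1 library that tested them, and Eda2r was not tested without an X-ray library.

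In wt thymus, death and arrest genes rose together. Bbc3 rose by 3.73 ± 0.14, Cdkn1a by 3.01 ± 0.12 and Bax, which permeabilises mitochondria, from 25.9 ± 1.66 to 160.0 ± 7.47 (2.61 ± 0.08; limma, Benjamini-Hochberg adjusted p = 1.02e-07). Phlda3 rose by 3.06 ± 0.12, Ccng1 by 2.73 ± 0.09, Aen by 2.69 ± 0.08, Sesn2 by 2.40 ± 0.12, Pmaip1 by 2.37 ± 0.12, Eda2r by 2.07 ± 0.16 and Mdm2 by 0.72 ± 0.07. The highest named genes included the stress cytokine gene Gdf15 (12.6 ± 7.22 against 0.158 ± 0.0338), Tnfsf4 (4.07 ± 0.19), the kinase gene Plk2 (3.68 ± 0.11), Dglucy (3.39 ± 0.12), Inka2 (3.29 ± 0.10) and Atf3 (3.24 ± 0.29). Myc fell from 43.5 ± 2.37 to 19.2 ± 2.59 (-1.17 ± 0.11). The DNA glycosylase gene Ung (-1.57 ± 0.14), the nucleolar gene Gnl3 (-1.40 ± 0.09), the chromatin remodeller gene Hells (-1.31 ± 0.10), Pprc1 (-1.13 ± 0.12), Cdca7 (-1.12 ± 0.13) and Shmt1 (-1.12 ± 0.09) also fell.

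Of 65 measured p53 targets in thymus, 45 rose and 2 fell (47 and 4 adjusted over the list alone), with a median of 1.17 (camera, adjusted p = 1.5e-26, and adjusted p = 0.00084 with an estimated correlation). The arrest list had 12 of 16 members up and the apoptosis list 12 of 15 (camera, Benjamini-Hochberg adjusted p = 2.33e-11 and 2.24e-12, and adjusted p = 0.0666 and 0.085 with an estimated correlation). Both cell cycle lists fell. In G2/M, 20 of 30 genes were called lower, including the mitotic cyclin gene Ccnb1 (-0.84 ± 0.11) and Cenpf (-0.62 ± 0.09), and in S phase 17 of 27, including Ccne2 (-1.10 ± 0.15) and Mcm4 (-0.66 ± 0.09). Their medians were -0.42 and -0.47 (camera, Benjamini-Hochberg adjusted p = 1.07e-09 for both, and adjusted p = 0.422 with an estimated correlation). The linker histone genes H1f2 (0.86 ± 0.10) and H1f3 (0.85 ± 0.16) rose among 5 measured histone genes (camera, Benjamini-Hochberg adjusted p = 0.00139, and adjusted p = 0.175 with an estimated correlation).

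Other groups moved in the irradiated thymus as well. Immediate early genes had 10 of 14 members up, with Fos at 3.01 ± 0.25 and Jun at 2.24 ± 0.20, and NF-kB genes 8 of 15, with the chemokine genes Ccl3 at 2.78 ± 0.30 and Ccl2 at 2.95 ± 0.34. For these lists camera gave Benjamini-Hochberg adjusted p = 2.22e-06 and 8.63e-06, and adjusted p = 0.422 with an estimated correlation for both. Cholesterol synthesis genes fell for 11 of 21 members, including Idi1 (-0.70 ± 0.10). Glucocorticoid-responsive genes rose for 7 of 11, including Tsc22d3 (0.94 ± 0.12) and the metallothionein gene Mt1 (1.14 ± 0.13). The latter lists shared a Benjamini-Hochberg adjusted camera p of 3.3e-05, with adjusted p = 0.422 for cholesterol synthesis and adjusted p = 0.175 for glucocorticoid response with an estimated correlation. Thymic epithelial markers, from the stroma rather than the thymocytes, rose for 5 of 10 members, with Krt8 at 338 ± 22.4 against 190.0 ± 5.47 (camera, Benjamini-Hochberg adjusted p = 0.000111, and adjusted p = 0.258 with an estimated correlation).

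Thymus had 2945 called genes of 13810 by limma with Benjamini-Hochberg adjustment, 1349 higher and 1596 lower, of which 224 differed by a log2 of at least 1. Groups did not overlap for 40.6% of genes, where chance gives 10%. The count was 1686 without untreated replicate 2, 1883 without untreated replicate 3 and 1576 without X-ray replicate 3.

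The effect of X-rays differed between wt tissues for 4770 of 15654 genes (limma interaction F test, Benjamini-Hochberg). Ei24 gave the highest F, 205, with log2 effects of 0.34 in liver, 2.27 in spleen and 2.27 in thymus. Bax (F = 121) stood at 0.56, 2.22 and 2.61, Tnfsf4 (F = 169) at 0.35, 3.81 and 4.07, and Bbc3 (F = 55.9) at -0.27, 3.85 and 3.73. Mef2b (F = 146) stood at 0.02, 3.19 and 0.11, and Eda2r (F = 35.2) at 3.58, 3.75 and 2.07. Trp53 was not called (F = 0.866). Pairwise, 4126 genes differed between spleen and liver, 2428 between thymus and liver and 1494 between spleen and thymus.

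The X-ray responses of the tissues shared genes beyond independent lists. Of genes tested in both tissues, 24 rose in liver and spleen (4.77 for independent lists), 24 in liver and thymus (2.59), and 692 in spleen and thymus (227), with Benjamini-Hochberg adjusted p = 1.01e-15, 2.05e-21 and 5.44e-222 (one-sided Fisher's exact test, 12 overlaps in the family). For falling genes spleen and thymus shared 684 (332, adjusted p = 1.06e-102, the same exact test). Rising in every tissue were 23 genes, 13 of them in the p53 lists: Aen, Apaf1, Ccng1, Cdkn1a, Ddit4, Eda2r, Phlda3, Polk, Sesn2, Tnfrsf10b, Trp53inp1, Zfp365 and Zmat3. The others were Cxcl10, Ddias, Ddit4l, Gask1b, Glipr1, Icam1, Inka2, Mmrn2, Zfp874a and Zfp958. By limma, 0 genes were called lower in all 3 tissues. In every paired-end tissue Xist was high in untreated replicate 1 and X-ray replicates 1 and 2, and under 1 in the others. Same-numbered libraries may thus come from the same animal. These overlap tests and the interaction test took the tissues as separate.

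The single-end libraries carried conflicting labels. All 18 were titled xray, but the characteristics called 9 libraries of the series control despite that title (those titled d24 liver, d24 thymus and wt spleen), and gave WT for the 9 titled d24. The titles define the groups here. Each library was placed on a scale on which the untreated paired-end mean is 0 and the X-ray mean 1, over the genes that X-rays raised by a log2 of at least 1 in that tissue. This sets levels of separately normalised tables side by side, after a shift to a common centre, and was not tested. The libraries titled wt xray lay at 0.161 ± 0.115 in liver, -0.0196 ± 0.0969 in spleen and -0.105 ± 0.0214 in thymus. Those titled d24 xray lay at 0.675 ± 0.152, 0.187 ± 0.136 and 0.308 ± 0.200. Cdkn1a in spleen was 7.40 ± 1.96 in the libraries titled wt xray, beside 4.98 ± 1.29 in untreated paired-end spleens, and 373 ± 49.3 in those titled d24 xray, above the 157 ± 6.19 of irradiated paired-end spleens.

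**Figure D2:**
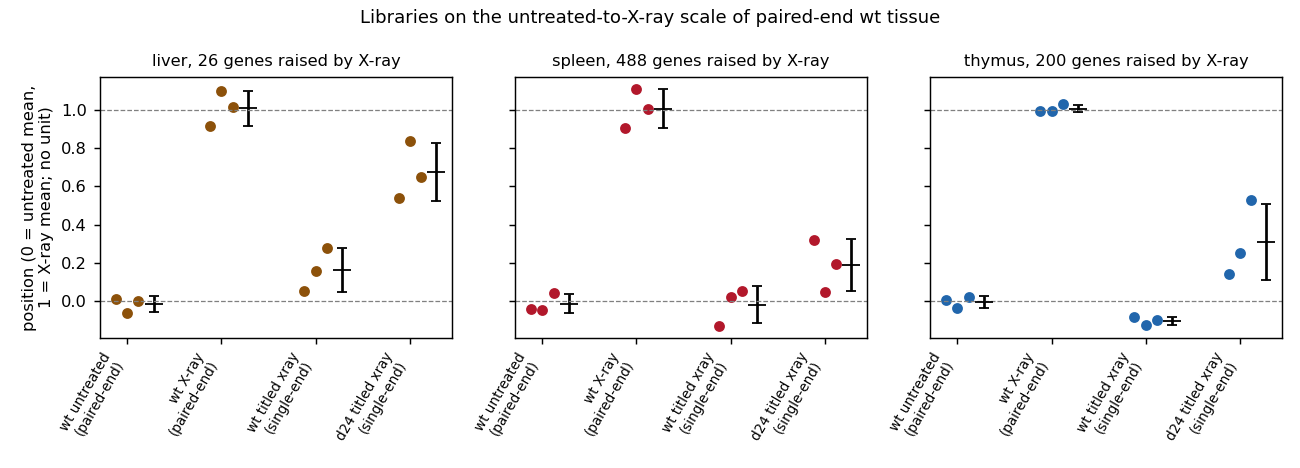
Position of each library between untreated (0) and irradiated (1) paired-end wt means, from 26 induced genes in liver, 488 in spleen and 200 in thymus; points are libraries and black marks the mean ± SD of 3. Libraries titled wt xray in the single-end table lay at 0.161 in liver, -0.0196 in spleen and -0.105 in thymus.

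The libraries titled d24 xray had more signal over the X-ray-induced genes than those titled wt xray. The median log2 difference was 0.91 over 26 such genes in liver (21 higher), 0.19 over 430 in spleen (265 higher) and 0.72 over 180 in thymus (156 higher). Benjamini-Hochberg adjusted camera p over the tissues was 9.88e-09, 8.79e-06 and 7.98e-18, and no tissue passed with an estimated correlation (adjusted p = 0.0618, 0.0782 and 0.0521). In liver the median was 0.60 without d24 replicate 2. In spleen it was 0.11 without d24 replicate 1, 0.31 without d24 replicate 2, 0.30 without wt replicate 3, 0.29 with quantile scaling and 0.10 over induced genes of any fold, and in thymus 0.41 without d24 replicate 3 and 0.37 over induced genes of any fold. Of the spleen genes, 25 were called higher in d24 and 8 lower. Outside the p53 lists the median was 0.44 over 12 genes in liver (7 higher and 5 lower in d24), 0.13 over 397 in spleen and 0.69 over 147 in thymus. There camera did not pass in liver (Benjamini-Hochberg adjusted p = 0.103) and passed in spleen and thymus (0.00201 and 2.15e-14, and adjusted p = 0.314 and 0.106 with an estimated correlation). Across all genes the d24 and X-ray effects had a Pearson correlation of 0.327 in liver, 0.105 in spleen and 0.372 in thymus (Spearman 0.329, 0.115 and 0.349). These correlations run across genes, which are not independent replicates.

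In liver, the libraries titled d24 xray had more Hamp and less of several granule genes than those titled wt xray. Hamp, which encodes the iron hormone hepcidin, was 709 ± 427 against 2.35 ± 2.71, a log2 difference of 8.32 ± 0.68 (limma, Benjamini-Hochberg adjusted p = 0.000864). Hamp also varied widely within paired-end wt groups, at 0.814, 101 and 0.333 in untreated and 0.371, 102 and 32.6 in X-ray livers. Elfn1 rose by 6.32 ± 0.43, the metallothionein gene Mt2 by 6.29 ± 0.82, Nnmt by 6.25 ± 0.89, the steroid hydroxylase gene Cyp17a1 by 6.21 ± 1.02 and Hapln1 by 4.81 ± 0.66. The phosphate hormone gene Fgf23 was also called higher, at 43.0, 311 and 5.76 in the d24 libraries and at most 0.166 in wt, so its fitted difference depends on the pseudocount. The granule genes of neutrophils and eosinophils were lower, with Ngp at -6.13 ± 0.90, Camp at -5.34 ± 0.63, Mpo at -4.54 ± 0.57, Ltf at -4.48 ± 0.80, Ear1 at -4.80 ± 0.61 and Prg2 at -4.73 ± 0.61, as was the B cell gene Pou2af1 (-4.34 ± 0.57). Among the panel, Cdkn1a (277 ± 147 against 66.2 ± 70) and Eda2r (8.59 ± 1.66 against 1.14 ± 1.97) did not pass (limma, Benjamini-Hochberg adjusted p = 0.177 and 0.116).

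The p53 targets in d24 liver had a median of 0.27 over 64 genes, of which 1, Btg2 (2.20 ± 0.38), was called higher and 0 lower, as when adjusted over the list alone (camera, adjusted p = 0.000403, and adjusted p = 0.0932 with an estimated correlation). Neutrophil and myeloid progenitor markers fell for 6 of 13 genes (11 adjusted over the list alone), including S100a8 (-4.06 ± 0.57) and S100a9 (-3.74 ± 0.46), and B cell markers for 3 of 9 (7 adjusted over the list alone), including Ighm (-2.89 ± 0.32). Their medians were -3.38 and -2.56 (camera, Benjamini-Hochberg adjusted p = 1.99e-12 and 1.16e-09, and adjusted p = 0.263 for both with an estimated correlation). The recombination genes Rag1 (-3.85 ± 0.54) and Dntt (-3.43 ± 0.63) and the heme synthesis gene Alas2 (-2.14 ± 0.38) fell with them. Gluconeogenesis genes had a median of 1.14, with 0 of 15 called over all genes by limma but 11 higher when adjusted over the list alone, among them Tat at 2.57 ± 0.57 and Igfbp1 at 1.77 ± 0.39. Cholesterol synthesis had a median of -0.98, with Hmgcs1 down by -2.46 ± 0.38 of 22 genes (8 lower adjusted over the list alone). For these metabolic lists camera gave Benjamini-Hochberg adjusted p = 4.08e-08 and 3e-06, and adjusted p = 0.263 and 0.408 with an estimated correlation. Interferon-responsive genes had a median of -0.76, with Zbp1 called lower (-2.05 ± 0.33; camera, Benjamini-Hochberg adjusted p = 2.17e-05, and adjusted p = 0.263 with an estimated correlation).

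Limma with Benjamini-Hochberg adjustment called 72 of 13695 genes in d24 liver, 38 higher and 34 lower, while edgeR called 11 and DESeq2 531. Groups did not overlap for 19.1% of genes, where chance gives 10%. The count was 13 without d24 replicate 1, 41 without d24 replicate 2, 311 without d24 replicate 3, 7 without wt replicate 1, 4 without wt replicate 2 and 47 without wt replicate 3. Of the 27 called genes picked by the naming rule, 4 (Hamp, Elfn1, Mpo and Rag1) were called in every such refit that tested them, and each of the others lost its call in at least 1 refit. Mpo and Rag1 lay at most at 0.561 and 0.374 in the d24 livers, so the filter left both untested without any 1 wt library. For these genes the refits without a wt library show nothing. The calls lost were 18 without d24 replicate 1, 9 without d24 replicate 2, 17 without wt replicate 1, 19 without wt replicate 2 and 7 without wt replicate 3, with Benjamini-Hochberg adjusted limma p up to 0.295 (Fcrla).

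**Figure D3:**
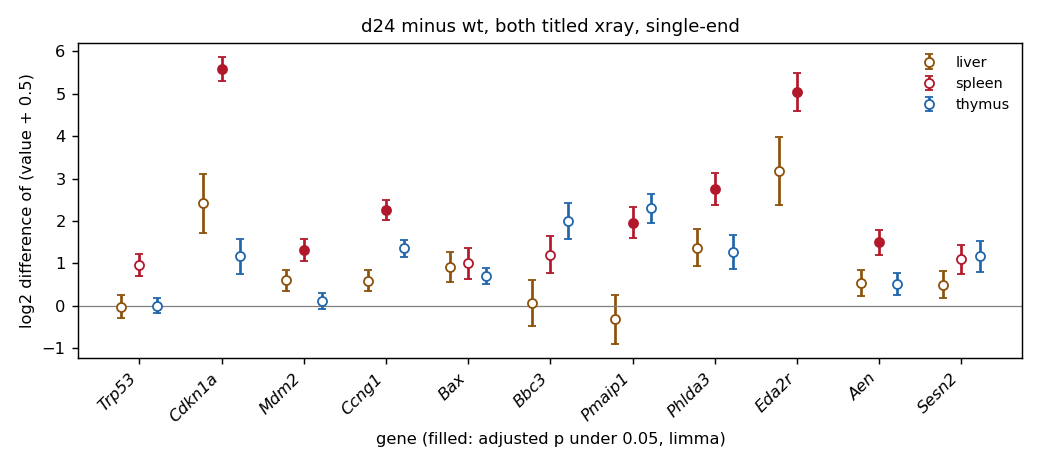
Log2 difference (d24 minus wt, ± SE, 3 against 3 single-end libraries titled xray) of the panel genes in liver, spleen and thymus, with filled points for Benjamini-Hochberg adjusted limma p under 0.05. Cdkn1a stood at 2.41 in liver, 5.59 in spleen and 1.16 in thymus, and Eda2r was not tested in thymus.

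In spleen, p53 targets were higher and granule and platelet genes far lower in the libraries titled d24 xray. Cdkn1a rose by 5.59 ± 0.28, Eda2r by 5.05 ± 0.45, Phlda3 by 2.76 ± 0.38 and Ccng1 by 2.26 ± 0.25 (limma, Benjamini-Hochberg adjusted p from 1.63e-06 to 0.0021). Pmaip1 (1.96 ± 0.37), Aen (1.50 ± 0.30) and Mdm2 (1.32 ± 0.26) also rose, while Bax (1.00 ± 0.36), Bbc3 (1.21 ± 0.43) and Sesn2 (1.10 ± 0.34) did not pass. The mast cell protease genes Tpsb2 (5.97 ± 0.61) and Mcpt4 (5.49 ± 0.71), Zfp750 (5.61 ± 0.49), Zfp365 (5.43 ± 0.51) and the cytidine deaminase gene Cda (4.50 ± 0.49) were the other highest named genes. Mpo, the peroxidase of neutrophil granules, was 0.461 ± 0.551 against 238 ± 70.8 (-8.08 ± 0.45; limma, Benjamini-Hochberg adjusted p = 2.17e-06). Elane (-6.09 ± 0.60), Prtn3 (-5.63 ± 0.60), Ctsg (-5.60 ± 0.67), Ms4a3 (-5.46 ± 0.75), Prg3 (-4.86 ± 0.71) and Fcnb (-4.84 ± 0.63), also expressed by granulocytes or their precursors, fell too.

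Of 64 p53 targets in d24 spleen, 14 rose and 0 fell (23 and 1 adjusted over the list alone), with a median of 0.44 (camera, adjusted p = 6.99e-09, and adjusted p = 0.0115 with an estimated correlation). Neutrophil and myeloid progenitor markers fell for 9 of 14 genes, with a median of -3.67 (camera, Benjamini-Hochberg adjusted p = 6.84e-15, and adjusted p = 0.256 with an estimated correlation). Megakaryocyte and platelet markers fell for 8 of 9, with the platelet chemokine genes Ppbp at 10.8 ± 3.44 against 330.5 ± 151 and Pf4 at -4.53 ± 0.46, and Treml1 at -4.75 ± 0.50. Their median was -3.47 (camera, Benjamini-Hochberg adjusted p = 1.67e-15), and this list alone of 16 passing lists held with an estimated correlation (adjusted p = 0.0463). Interferon-responsive genes fell for 5 of 23 (14 adjusted over the list alone), including Oasl1 (-3.35 ± 0.60) and Ifit1 (-3.39 ± 0.69), with a median of -1.59 (camera, Benjamini-Hochberg adjusted p = 1.4e-10, and adjusted p = 0.349 with an estimated correlation). B cell markers fell for 1 gene, Cd79b (-2.08 ± 0.43), of 13 (8 adjusted over the list alone), with a median of -1.60 (camera, Benjamini-Hochberg adjusted p = 4.18e-05, and adjusted p = 0.57 with an estimated correlation). The histone genes H1f1 (-2.85 ± 0.63) and H1f3 (-2.42 ± 0.46) fell among 5 (camera, Benjamini-Hochberg adjusted p = 2.01e-06, and adjusted p = 0.181 with an estimated correlation).

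**Figure D4:**
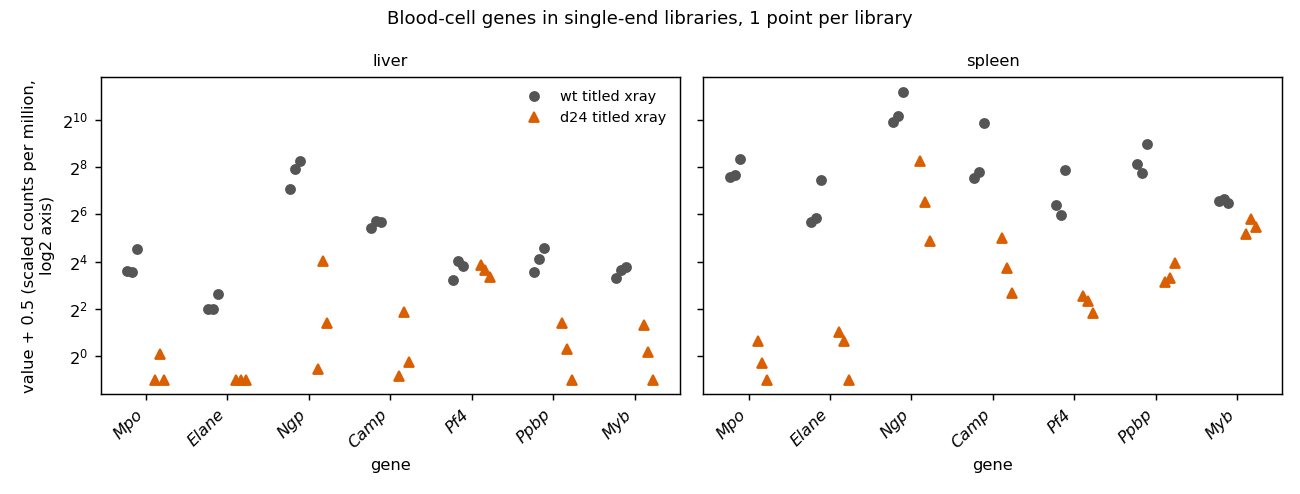
Normalised signal plus 0.5 on a log2 axis of Mpo, Elane, Ngp, Camp, Pf4, Ppbp and Myb in each single-end liver and spleen library titled wt xray or d24 xray. Mpo in spleen averaged 0.461 in d24 and 238 in wt.

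Limma with Benjamini-Hochberg adjustment called 309 of 13554 genes in d24 spleen, 141 higher and 168 lower, edgeR 145 and DESeq2 597. Groups did not overlap for 19.3% of genes, where chance gives 10%. The count was 119 without d24 replicate 2 and 164 without d24 replicate 3, and 45 with Xist, the marker of female libraries, as a covariate. Xist stood at 546 to 702 in the 3 d24 spleens and at 0.925, 830 and 0.376 in the wt spleens, so sex differed along with genotype. Of 39 called genes picked by that rule, 23 were called in every refit without 1 library that tested them, among them Cdkn1a, Eda2r, Phlda3, Ccng1, Mpo, Elane, Ppbp and Pf4. Mdm2 lost its call without any 1 of the d24 libraries or wt replicate 2, and Oasl1 without d24 replicate 2 or wt replicate 3. Ifit1 lost it without any 1 d24 library, Cd79b without d24 replicate 2, d24 replicate 3 or wt replicate 3, Pmaip1 without d24 replicate 1 or 3, and Aen without d24 replicate 1, d24 replicate 2 or wt replicate 2. H1f3 was lost without any 1 wt library and H1f1 without d24 replicate 1 or 2. Over these refits the highest Benjamini-Hochberg adjusted limma p was 0.129, for Ifit1 without d24 replicate 2.

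In thymus, 1 gene passed between the libraries titled d24 xray and wt xray. Tnc, which encodes the matrix protein tenascin C, was 264 ± 22.4 against 91.4 ± 13.8, a log2 difference of 1.53 ± 0.16 (limma, Benjamini-Hochberg adjusted p = 0.0238). Pmaip1 (29.8 ± 2.97 against 5.92 ± 2.26) and Ccng1 (252 ± 57.8 against 97.6 ± 16.7) were the nearest panel genes and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0763 for both). Tnc was the call of limma among 13818 genes, of which 1359 had an unadjusted p under 0.05, while edgeR called 2 and DESeq2 266. The count was 4 without d24 replicate 2, 71 without d24 replicate 3 and 0 without any 1 of the wt libraries, and Tnc had a Benjamini-Hochberg adjusted p of 0.449 without wt replicate 3. Without d24 replicate 1 that p for Tnc was 0.0508. Groups did not overlap for 16.6% of genes, where chance gives 10%.

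The p53 targets in d24 thymus had a median of 0.35 over 63 genes, 13 of them higher when adjusted over the list alone and 0 over all genes tested by limma (camera, adjusted p = 1.28e-05, and adjusted p = 0.00515 with an estimated correlation). Without d24 replicate 3 that median was 0.21. Fatty acid oxidation genes lay higher, all 19 with a positive difference, a median of 0.68 and Cpt1a, the carnitine shuttle enzyme, at 0.83 ± 0.20 (camera, Benjamini-Hochberg adjusted p = 1.61e-05, and adjusted p = 0.43 with an estimated correlation). Cholesterol synthesis lay lower, with a median of -0.74 (camera, Benjamini-Hochberg adjusted p = 1.61e-05, and adjusted p = 0.432 with an estimated correlation). Markers of cells outside the thymocyte lineage moved with these groups. Hepatocyte markers had a median of 2.53 over 7 genes, with Alb at 793 in d24 replicate 3 against a wt mean of 2.23 ± 2.13, and fibroblast markers, with Col1a2 at 1.67 ± 0.38, had a median of 1.40 (camera, Benjamini-Hochberg adjusted p = 0.0003 and 0.000551, and adjusted p = 0.43 for both with an estimated correlation).

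The d24 effect differed between tissues for 159 of 16092 genes (limma interaction F test, Benjamini-Hochberg). Zfp750 (F = 49.2) had log2 effects of -0.01 in liver, 5.61 in spleen and 0.54 in thymus. Hamp (F = 39.6) stood at 8.32, 0 and 0.79. Its signal was 0 in every d24 spleen library and 1.22 ± 1.15 in d24 thymus. At such levels a weaker response cannot be told apart from absent expression. Pf4 (F = 35.6) stood at -0.07, -4.53 and 0.68, and Mpo (F = 33.6) at -4.54, -8.08 and 0.35. Among the panel, Cdkn1a (F = 15.2) at 2.41, 5.59 and 1.16 and Ccng1 (F = 15.4) at 0.59, 2.26 and 1.35 were called (limma, Benjamini-Hochberg adjusted p = 0.021 and 0.0204). The count was 253 without d24 liver replicate 3, 84 without wt liver replicate 1, 90 without wt liver replicate 2, 95 without wt spleen replicate 1, 86 without wt spleen replicate 2 and 96 without wt thymus replicate 1, with edgeR at 46 and DESeq2 at 504. Of the genes tested in both tissues, liver and spleen shared 18 lower calls, against 0.319 for independent lists, and 4 higher calls, against 0.181 (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 2.86e-28 and 5.45e-05).

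The labels do not say that the 3 libraries of a group came from separate animals. The limma p-values thus measure the spread between these samples only. For the overlaps, the exact test counts genes as independent units, so its p-values do not measure spread between libraries. Camera p-values with the preset correlation also rest on that assumed correlation between genes.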

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

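The tests of the layout, of the treatment labels, of a full X-ray response in d24 and of an outlying library or the sex of the animals behind the blood-cell genes were chosen after the result was seen, as were the covariate for sex and the refits without libraries that stood apart. The other tests here were written before their result was seen.

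X-ray effects that differed between wt tissues were found by the interaction test for 4770 genes. Those named are Ei24 (F = 205), Tnfsf4 (169), Mef2b (146), Hmcn2 (135), Cep170b (134), Bax (121), Dcxr (117) and Mreg (115). In the panel they are Bbc3 (F = 55.9), Mdm2 (48.4), Cdkn1a (46.7), Ccng1 (35.8), Eda2r (35.2), Phlda3 (26.3), Pmaip1 (24.7), Aen (16.8) and Sesn2 (13.2). Genotype effects that differed between tissues were found for 159 genes, among them Zfp750 (F = 49.2), Itgb3 (40.2), Hamp (39.6), Cda (39.5), Pf4 (35.6), Elane (34.1), Mpo (33.6), Ccng1 (15.4) and Cdkn1a (15.2). Hamp had a signal of 0 in every d24 spleen library, so its effect there marks absent signal. Of 100 regroupings of the libraries within tissues, the real one included, 1 gave as many genes for X-rays, the real one (4770, highest other 2443), and 1 for genotype (159, highest other 100). These regroupings take away the effect itself along with its difference between tissues, so they do not test that difference.

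The single-end libraries titled wt xray lay near the untreated level of X-ray-induced genes in spleen and thymus, at -0.0196 ± 0.0969 and -0.105 ± 0.0214 (-0.0170 and -0.0467 over p53 targets). A layout or scaling that hides induction fully is argued against by the d24 libraries of the same table. They lay higher by 0.412 (SE 0.116) in thymus and 0.514 (SE 0.110) in liver. In spleen the difference was 0.206 (SE 0.0964), short of the margin set for this test, but 0.589 (SE 0.0453) over p53 targets. Such differences cannot decide on a layout or scaling that only weakens induction. Libraries not irradiated despite their title would lie near the untreated level, and a wrong treatment label may account for the pattern in spleen and thymus. The characteristics call the wt spleen libraries control. They give 2 Gy and 3 h for the wt thymus libraries, where title and characteristics would both have to be wrong. In liver, unirradiated and irradiated libraries cannot be told apart, since the mean position was 0.161 ± 0.115 over induced genes but 0.189 ± 0.0783 over p53 targets, above 0 by more than 2 SD, and Cdkn1a stood at 17.7, 34.4 and 147. A weaker response of wt animals that differ from the paired-end ones, for example in age, was not tested and stays open.

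Neutrophil and B cell marker lists were lower in the d24 libraries of liver and spleen, and the platelet list in spleen. With an estimated correlation, camera held for the platelet list alone. X-rays alone are argued against in spleen, where the genes called lower in d24 had a median X-ray effect in wt of 0.42 (154 genes, 114 positive), while in liver (-0.11, 22 genes, 10 positive) this cannot be told apart, since 12 of the 34 genes called lower had an untreated level of at least 5 in paired-end livers. A single outlying library is argued against by fixed lists, picked here because they were low in these same comparisons. Leaving out 1 library weakened the median over neutrophil and B cell markers in liver at most to -2.47, from -2.79, with 17 of 22 genes measured. Over these and platelet markers in spleen the median weakened at most to -1.66, from -2.04. The highest camera p of these refits was 3.16e-15 in liver and 2.59e-20 in spleen with the preset correlation, and none used an estimated one. The sex of the animals is argued against in liver by a median over these lists of -2.95 with Xist as a covariate. In spleen that median was -2.24, which cannot decide, since all d24 spleens but only 1 wt spleen were female. Younger wt livers, which would carry more blood-forming cells, are argued against by perinatal liver genes. Those genes lay higher in d24 by a median of 0.65 (8 higher and 3 lower of 11 measured, with a lowest Benjamini-Hochberg adjusted limma p of 0.117). The libraries titled wt xray stood high for some of these genes. Ngp was 4.66 ± 2.32 in untreated and 6.07 ± 1.86 in X-ray paired-end livers. In d24 livers it was 0.187, 15.9 and 2.18, so their mean of 6.08 ± 8.53 rests mainly on replicate 2. Perinatal liver genes also set the single-end livers apart from the paired-end ones. Mpo was 17.4 ± 6.78 and 29.5 ± 12.0 in paired-end spleens, between the d24 and single-end wt levels. The tables were normalised separately, so this was not tested. Whether d24 tissues held fewer of these cells or less of these transcripts per cell was not tested and stays open, as do effects of X-rays that only d24 animals have.

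As a set, the p53 target genes were higher in d24 than in wt libraries titled xray. In liver the set did not pass with an estimated correlation. Of single members, Btg2 alone passed in liver and none in thymus. Btg2 lost that call without d24 replicate 1, d24 replicate 2 or any 1 wt library. Over the p53 targets that X-rays raised in paired-end wt tissues, the mean position of the d24 libraries was 0.844 ± 0.166 in liver (14 genes, upper end of the 95% interval 1.26), 0.572 ± 0.0781 in spleen (35 genes, 0.766) and 0.350 ± 0.0540 in thymus (36 genes, 0.484), and 4 of the spleen genes, among them Cdkn1a and Eda2r, lay above 1. A full X-ray response in d24 set against unirradiated wt cannot be told apart from a partial one or from p53 activity without X-rays, since no library here shows how strongly the wt animals of the single-end table respond. In spleen the d24 minus wt median over the p53 target lists was 0.44 with Xist as a covariate. That cannot decide on the sex of the animals, since all d24 spleens but only 1 wt spleen were female. An outlying library in thymus is argued against by a median of 0.21 without d24 replicate 3 (camera, adjusted p = 9.06e-06), down from 0.35. The characteristics call the d24 liver and thymus libraries control, so whether these animals were irradiated also stays open.

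With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For each count and median named next, except the last, 1 of the 10 splits gave a value as high, the real one. For X-rays the counts were 32, 5351 and 2945 in liver, spleen and thymus, beside 5 in each tissue for the highest other split, the one that parts the libraries by sex. In X-ray spleen, where the numbers pair the libraries, 3 other splits part as many pairs as the real one, and each called 0 genes. The medians over p53 targets after X-rays were 0.23 (highest other 0.21), 1.30 (-0.53) and 1.17 (-0.51). For d24 the counts were 72 (highest other 5), 309 (0) and 1 (0), and the p53 medians 0.27 (-0.20), 0.44 (0.31) and 0.35 (0.20). The medians over X-ray-induced genes in d24 were 0.91 (highest other -0.66) in liver and 0.72 (-0.37) in thymus. In spleen 3 of 10 splits gave a median as high as the real 0.19, the highest other being 0.25.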

How the results depend on the processing

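The covariate for sex and the refits without libraries that differ in clock genes or stand apart were chosen after the data were seen. Of 254 called genes picked by the naming rule, 162 kept direction and call in every alternative, and over 4470 refits 4007 kept both, 463 lost the call and 0 reversed. Of 240 picked genes that were not called, 259 of 4247 refits called them in the same direction. Called lists gave 1521 refits, of which 167 lost the call and 2 reversed. Where 1 library of a group was left, it was assumed to vary like the other groups. The cause was not tested for any shift below, except that leaving out libraries leaves fewer samples.

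DESeq2 called 631 genes in X-ray liver, 531, 597 and 266 in d24 liver, spleen and thymus and 504 in the genotype interaction; edgeR called 11, 145 and 2 in the d24 tissues and 46 in that interaction. A fit of all libraries of a table called 1715 in X-ray liver (783 higher and 932 lower), 1940 in X-ray thymus, 305 in d24 liver and 140 in d24 thymus. With an absolute log2 of at least 1, 799 passed in X-ray spleen and 224 in X-ray thymus. With Xist as covariate the counts were 19 in X-ray liver, 45 in d24 spleen and 0 in d24 thymus, where 1092 genes had an unadjusted limma p under 0.05 in that fit. Without the liver libraries that differ in clock genes, X-ray liver had 14. In d24 liver a pseudocount of 0.1 gave 44, no filter 43, the stricter filter 46 and limma without trend 47. In d24 spleen no filter gave 159 and no trend 197. In d24 thymus a pseudocount of 2 gave 2, quantile scaling 2 and no filter 0 (1624 at an unadjusted limma p under 0.05). The stricter filter gave 92 in the genotype interaction.

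The replicate block gave 39, 5709 and 4270 genes in X-ray liver, spleen and thymus and 33, 574 and 0 in the d24 tissues (1221 at an unadjusted limma p under 0.05 in thymus), and the pairing rule was met in X-ray spleen alone, where the block changed no call of a named gene or list. In the d24 comparisons the correlations of same-numbered libraries ran from -0.268 to 0.00683, so they share only a number. Every sample correlated best with its own number in X-ray spleen and in no other comparison, which is a hint from the data and not from the design.

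Leaving out 1 library gave 9 to 2836 genes in X-ray liver, 3136 to 7037 in X-ray spleen and 1576 to 2851 in X-ray thymus, 4 to 311 in d24 liver, 119 to 241 in d24 spleen and 0 to 71 in d24 thymus, 3470 to 6403 in the X-ray interaction and 84 to 253 in the genotype interaction. In d24 thymus the G2/M list ranged from -0.49 to 0.14 and the S phase list from -0.82 to 0.22; both turned positive without d24 replicate 3 (camera, Benjamini-Hochberg adjusted p = 0.0166 and 0.00686). With an estimated camera correlation the d24 median over p53 targets in liver (0.27) no longer passed, nor, with Benjamini-Hochberg adjustment over the tissues, did those over X-ray-induced genes in liver (0.91), spleen (0.19) and thymus (0.72). No scaling moved the median of all genes by over 0.1. Depth limits genes near 1 read, and the d24 comparisons missed most simulated changes of 1 on the log2 scale.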

Other observations

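The tests of separate scaling below were chosen after the result was seen, and the test on adult liver genes was written before its result.

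Other groups moved in the irradiated spleens. Interferon-responsive genes had 7 of 24 members up, with Mx1 at 1.70 ± 0.18 and Cxcl10 at 1.87 ± 0.24 (camera, Benjamini-Hochberg adjusted p = 0.0132, and adjusted p = 0.792 with an estimated correlation), and that list was lost without untreated replicate 2 (median 0.18). Plasma cell markers rose for 3 of 6 genes, including Mzb1 (1.07 ± 0.13) and Irf4 (1.29 ± 0.21), with a Benjamini-Hochberg adjusted camera p of 0.00989 and adjusted p = 0.499 with an estimated correlation. Clock genes rose for 8 of 18, with Bhlhe41 at 1.96 ± 0.18 and Tef at 1.42 ± 0.15 (camera, Benjamini-Hochberg adjusted p = 0.00402, and adjusted p = 0.573 with an estimated correlation). In irradiated thymus, genes of fatty acid oxidation rose for 4 of 19, including Acot1 (1.23 ± 0.15) and the lipid droplet gene Plin2 (0.70 ± 0.11), with a Benjamini-Hochberg adjusted camera p of 0.000763 and adjusted p = 0.422 with an estimated correlation. Markers of other cell types were higher in the same thymus libraries. All 11 measured hepatocyte markers had a positive difference, with a median of 1.49 and Alb at 951 in X-ray replicate 3 beside 33.5 and 63.5 in the others (camera, Benjamini-Hochberg adjusted p = 0.0134, and adjusted p = 0.653 with an estimated correlation). Neutrophil markers rose for 5 of 8 genes (camera, Benjamini-Hochberg adjusted p = 0.00317, and adjusted p = 0.422 with an estimated correlation) and macrophage markers for 4 of 10 (camera, Benjamini-Hochberg adjusted p = 0.0276, and adjusted p = 0.624 with an estimated correlation).

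In the spleens titled d24 xray, markers of NK cells had a median of -1.85 over 6 genes, 4 of them lower when adjusted over the list alone and 0 over all genes by limma, with Ncr1 at -2.24 ± 0.73 (camera, Benjamini-Hochberg adjusted p = 0.00122, and adjusted p = 0.264 with an estimated correlation). In the livers titled d24 xray, immediate early genes had a median of 1.01, with Jun called higher (2.18 ± 0.36; camera, Benjamini-Hochberg adjusted p = 0.000228, and adjusted p = 0.302 with an estimated correlation). Jun lost that call without d24 replicate 1, d24 replicate 2 or any 1 wt library. Endothelial markers had a median of 0.52 there, with Lyve1 at 1.61 ± 0.45 and 0 of 9 genes called by limma (camera, Benjamini-Hochberg adjusted p = 0.000336, and adjusted p = 0.263 with an estimated correlation).

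Single libraries stood apart in the single-end table. In d24 thymus replicate 3 the hemoglobin gene Hbb-b1 stood at 7003 beside 14.0 and 28.8 in the other d24 thymus libraries. In the spleens titled wt xray, replicate 3 had Hbb-b1 at 87480 beside 26950 and 27320. Leaving out both libraries, as chosen after the data were seen, gave 107 genes in the genotype interaction, 84 of them shared with the 159. Mitochondrial genes took 12.4% to 19.6% of reads in single-end livers and 7.07% to 11.3% in paired-end livers. Their share was 8.45% to 11.3% in X-ray against 7.07% to 8.13% in untreated livers. It was 4.93% to 6.24% in d24 against 4.355% to 4.59% in wt spleens, and 5.12% to 7.46% against 4.77% to 4.88% in thymus. In X-ray spleen, X-ray thymus and d24 liver the compared groups overlapped. Its bearing on the gene differences was not tested.

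Perinatal liver genes were far higher in the single-end wt livers. Afp, the fetal counterpart of albumin, was 6350.1 ± 2388 there and 16579 ± 609 in d24, beside 10.4 ± 0.860 in untreated paired-end livers. H19 was 26469 ± 8839 in single-end wt livers beside 345 ± 194. Separate scaling of the tables is argued against, since group means of perinatal genes differed by a median log2 of 3.01 (11 genes) and all genes by 0.05. The hypothesis that the single-end animals were younger may hold, but its test was open, because adult sex-biased liver genes had a median of -0.86 between the highest library of each group, the planned measure, and of -1.27 between group means, with 13 of 21 lower in the single-end libraries. The labels give no age.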
